A study of Mus musculus and Rattus norvegicus with 30 samples.

How the data were processed

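The rat data were read from the authors' deposited count table, which also carries log2 fold changes and p-values from the authors' own comparisons and coordinates per gene. The mouse data were read from 18 deposited tables of estimated counts per transcript. Per the submitters' processing notes the rat reads were handled with HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3 and DESeq2 1.20.0 on rn6. Per the submitters' processing notes the mouse reads passed through fastp, Salmon and DESeq2, without versions or a stated build. The rat values are counts per the file headers, and all of them were whole numbers. The mouse values are estimated counts per the file headers, of which 140790 transcripts were summed to 54307 genes. After summing, 7.79% of the mouse values were not whole and were rounded. The log2 fold changes and p-values of the deposited rat table are the authors', and were used only to count calls shared with the fits here. The deposited FPKM and TPM values and the authors' group means were not used.

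The rat table held 32545 genes, 9390 of them without a count in any library, and the mouse tables held 28190 genes without a count. Genes were kept by filterByExpr of edgeR with a minimum count of 10, which left 15181 rat and 14047 mouse genes. The fits were run in R 4.3.3 with edgeR 4.0.16, with TMM scaling and the robust quasi-likelihood F-test, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. The 12 rat libraries were fitted together as 4 groups, and the 18 mouse libraries as 4 groups with a term for the sequencing run. The run was read from the deposited file names: replicates 1 to 3 of each mouse group came from the first run and replicates 4 and 5 from the second, so sham vehicle hearts were in the first run only. Differences between effects were contrasts in the same fits. CPM values use TMM-scaled library sizes, and errors beside group means are SDs over libraries. TMM factors ran from 0.954 to 1.06 in rat and from 0.884 to 1.15 in mouse, and the biological coefficient of variation was 0.104 and 0.117.

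Gene lists, tests, covariates, the rule for named genes and the alternatives were fixed before the data were examined. The lists were the ERR family and coactivators, fatty acid uptake and oxidation, the TCA cycle and pyruvate dehydrogenase, the nuclear-encoded respiratory chain, mitochondrially encoded genes, mitochondrial biogenesis with dynamics and antioxidants, ketone and branched-chain amino acid oxidation, glycolysis, cardiac stress markers, adult contraction with calcium and conduction, extracellular matrix and fibrosis, cell cycle and E2F targets, autophagy and lysosome, inflammatory cytokines and adhesion, the integrated stress response, the aryl hydrocarbon and oxidative stress response, cholesterol synthesis, immediate early genes, the circadian clock, markers of fibroblasts, endothelium, macrophages and leukocytes, smooth muscle and pericytes, and blood, adipocytes and nerve, and sex-linked genes. These 25 lists held 483 entries, written from general knowledge of the genes. Each list with at least 5 tested members was tested with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the residuals. Counts of members that rose or fell use the adjustment over all genes unless the list alone is named.

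Genes were named by 3 rules: the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM and CPM ranges that did not overlap, up to 4 members with the smallest adjusted p from each list that passed or had at least 3 called members, and a fixed set of 10 (Esrra, Esrrb, Esrrg, Ppargc1a, Pdk4, Cpt1b, Nppa, Nppb, Myh7 and Myh6). Differences of effects were named by the 4 largest in each direction. Single results of 5 genes are not reported here, and these genes still count in the totals and lists. Overlaps sharing control libraries were set beside 20 simulated draws of unchanged groups against the same controls. The alternatives fixed in advance were RLE size factors, no low-count filter, a stricter filter, the Wald test of DESeq2 1.42.0, only the groups compared, the replicate number as a block, each library left out, no run term and each run alone. A clock score term, the first principal component of the run-centred clock genes (85.5% of their variance), and the removal of mitochondrially encoded genes were chosen after seeing the data.

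The fits were tested on simulated data with 200 changed genes in each comparison. At a log2 change of 1, 71%, 70% and 73% of changed genes were recovered for 915 in scramble cells, 915 in knockdown cells and the knockdown, and 62% for the difference of the 915 effects. In mouse 80% were recovered for TAC, 84% for 332 in TAC, 79% for 332 in sham and 65% for the difference of the 332 effects. At a log2 change of 0.5 these shares were 47%, 48%, 49%, 28%, 39%, 53%, 37% and 20%. False calls were 3 to 12 among 88 to 145 calls.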

Results

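Poly(A) RNA was sequenced from 2 preparations, each treated with an agonist of the estrogen-related receptors (ERR alpha, beta and gamma), orphan nuclear receptors that drive transcription of mitochondrial and fatty acid oxidation genes. The first set held 12 libraries of neonatal rat ventricular myocytes (NRVM, beating heart muscle cells isolated from pups of 3 days). The cells carried 25 nM of siRNA against ERR alpha and ERR gamma or a scrambled siRNA, and received the agonist 915 at 10 µM or DMSO vehicle for 24 hours, with 3 libraries in each of the 4 groups. The second set held 18 libraries of mouse left ventricle after transverse aortic constriction (TAC), an operation that overloads the heart with pressure, or after sham surgery. The mice were given the agonist 332 or vehicle for 6 weeks, with 5 sham hearts on 332, 3 sham hearts on vehicle, 5 TAC hearts on 332 and 5 TAC hearts on vehicle. Rat libraries held 12013379 to 18315341 counts and mouse libraries 11375894 to 16599899. The labels do not say whether rat replicates of a group came from separate isolations or separate dishes, so independence of the rat replicates could not be established.

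Both targeted genes were low in every library labelled as knockdown. Esrra, which encodes ERR alpha (ENSRNOG00000021139, chromosome 1, 222168730 to 222178725 in build rn6), stood at 199, 178 and 170 CPM (counts scaled to a common library size) in the 3 scramble vehicle libraries and at 14.0, 22.0 and 16.1 CPM in the 3 knockdown vehicle libraries. With 915 it stood at 227, 228 and 229 CPM in scramble cells and at 12.7, 13.5 and 18.9 CPM in knockdown cells. Esrrg, which encodes ERR gamma (ENSRNOG00000002593, chromosome 13, 106463368 to 106683436), gave 131, 130 and 131 CPM with the scramble siRNA and 18.7, 18.1 and 17.5 CPM with the knockdown. With 915 its values were 263, 273 and 302 CPM in scramble cells and 25.1, 16.1 and 22.2 CPM in knockdown cells. Esrrb, the untargeted family member, lay between 3.01 and 4.43 CPM in scramble vehicle cells and between 0.665 and 1.19 CPM in knockdown vehicle cells.

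Loss of both receptors lowered the transcripts of energy metabolism and of the contractile apparatus in vehicle-treated myocytes. Esrra fell by 3.39 on the log2 scale (SE 0.17), Esrrg by 2.85 (SE 0.11) and Esrrb by 1.88 (SE 0.27), with n = 3 libraries per group. Perm1, a muscle regulator that acts with the ERR coactivator PGC-1, fell by 3.68 (SE 0.08), from 104 ± 0.562 CPM (SD, n = 3) to 8.05 ± 0.606 CPM. Mb, which encodes the oxygen store myoglobin, dropped from 542 ± 28.2 to 56.6 ± 9.81 CPM, a log2 change of −3.26 (SE 0.12). Trim50, a ubiquitin ligase gene, showed the lowest fold change of the named genes at −5.00 (SE 0.15), and Myom2, a protein of the sarcomeric M band, at −3.37 (SE 0.07) and Tmem179 at −3.32 (SE 0.10) were also among the lowest.

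Of the 29 fatty acid uptake and oxidation genes, 28 fell, 1 rose and all 29 passed the test (median log2 change −0.98). Acadm, the medium-chain acyl-CoA dehydrogenase, changed by −1.96 (SE 0.07, adjusted p = 3.64e-14). Cpt2 of the carnitine shuttle changed by −1.49 (SE 0.06) and Cpt1b, its muscle-type entry enzyme, by −1.20 (SE 0.07). All 19 genes of the TCA cycle and pyruvate dehydrogenase fell, among them Idh2 at −1.61 (SE 0.05) and Dlst at −1.02 (SE 0.05). In the respiratory chain 65 of 66 nuclear-encoded genes fell (median −0.68), for example Cycs, which encodes cytochrome c, at −1.27 (SE 0.06) and Sdha of complex II at −1.11 (SE 0.05). The share of counts from the mitochondrial genome was 6.13% ± 0.539 (SD, n = 3) in scramble vehicle cells and 4.87% ± 0.398 in knockdown vehicle cells. Among mitochondrially encoded genes 12 of 13 fell, with Mt-cytb at −0.61 (SE 0.07), and the list's adjusted p of 2.7e-08 became adjusted p = 0.184 with an estimated correlation. Of the 18 genes for mitochondrial biogenesis, dynamics and antioxidants 11 fell and none rose, including the phosphate carrier Slc25a3 at −0.86 (SE 0.05). Ketone and branched-chain amino acid oxidation had 15 of 18 genes lower and 1 higher, with Acat1 at −1.10 (SE 0.07). Glycolysis had 17 of 22 genes lower, led by Slc2a4, the insulin-responsive glucose transporter, at −1.18 (SE 0.09), while Tpi1 at 7.05 CPM or less was uncertain because near-identical copies can take its reads.

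The genes of adult contraction, calcium handling and conduction followed, with 16 of 23 lower and none higher. Ckm, the muscle creatine kinase, changed by −2.05 (SE 0.08), Atp2a2, the calcium pump of the sarcoplasmic reticulum, by −0.93 (SE 0.06) and Gja1, a gap junction protein, by −0.65 (SE 0.06). Both myosin heavy chains were lower, Myh6 at −1.96 (SE 0.12) and Myh7 at −1.98 (SE 0.14). Of the 15 cardiac stress markers 4 rose and 4 fell, and the list did not pass (adjusted p = 0.0645). Rcan1, a calcineurin target, changed by −1.20 (SE 0.06) and Tgfb2 by 0.44 (SE 0.05), whereas Nppa at −0.06 (SE 0.12, adjusted p = 0.775) and Nppb at −0.27 (SE 0.15, adjusted p = 0.261) did not pass. The coactivator gene Ppargc1a stood at 26.4 ± 0.735 CPM against 23.4 ± 2.53 CPM (log2 0.17, SE 0.10, adjusted p = 0.257). Cholesterol synthesis had 10 of 15 genes lower and 1 higher, such as Idi1 at −0.98 (SE 0.10). Inflammatory cytokines and adhesion had 7 of 13 genes higher and none lower, including Cxcl1 at 0.64 (SE 0.11) and Ccl7 at 0.62 (SE 0.10). The macrophage and leukocyte markers had 3 of 7 genes higher, with the lysozyme gene Lyz2 at 1.22 (SE 0.15) and Csf1r at 0.46 (SE 0.12), and that list's adjusted p of 0.00865 became adjusted p = 0.0669 with an estimated correlation. Other genes with large rises were Mmp12, a macrophage elastase, at 1.66 (SE 0.25), Col4a4 at 1.32 (SE 0.07) and the exocytosis gene Stxbp6 at 1.27 (SE 0.09). The immediate early genes had 6 of 13 higher and 1 lower, with Egr1 at 0.50 (SE 0.09), and their adjusted p of 0.0356 became adjusted p = 0.274 with an estimated correlation.

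By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3099 of 15181 genes changed with the knockdown, 1176 higher and 1923 lower, and 81 of those rose and 246 fell at least 2-fold. Of 23 lists tested, 13 passed the camera test and 10 still passed with an estimated correlation. Extracellular matrix (4 higher and 2 lower of 24), cell cycle (2 lower of 28), autophagy and lysosome (5 higher and 6 lower of 29), the integrated stress response (4 lower of 16) and the aryl hydrocarbon and oxidative stress response (1 higher and 3 lower of 12) did not pass, nor did the clock genes (5 higher of 15). Markers of fibroblasts (2 higher of 12), endothelium (2 higher of 9) and smooth muscle (1 lower of 8) did not pass either. For the matrix and autophagy lists the median and the mean differed in sign. The rat blood, adipocyte and nerve list and the sex-linked list had 4 genes each above the expression filter, too few for a list test, and 0 of either changed with the knockdown. In the authors' deposited comparison 2810 genes had an adjusted p below 0.05, and 2636 genes were called in both with 0 of opposite sign.

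**Figure D1:**
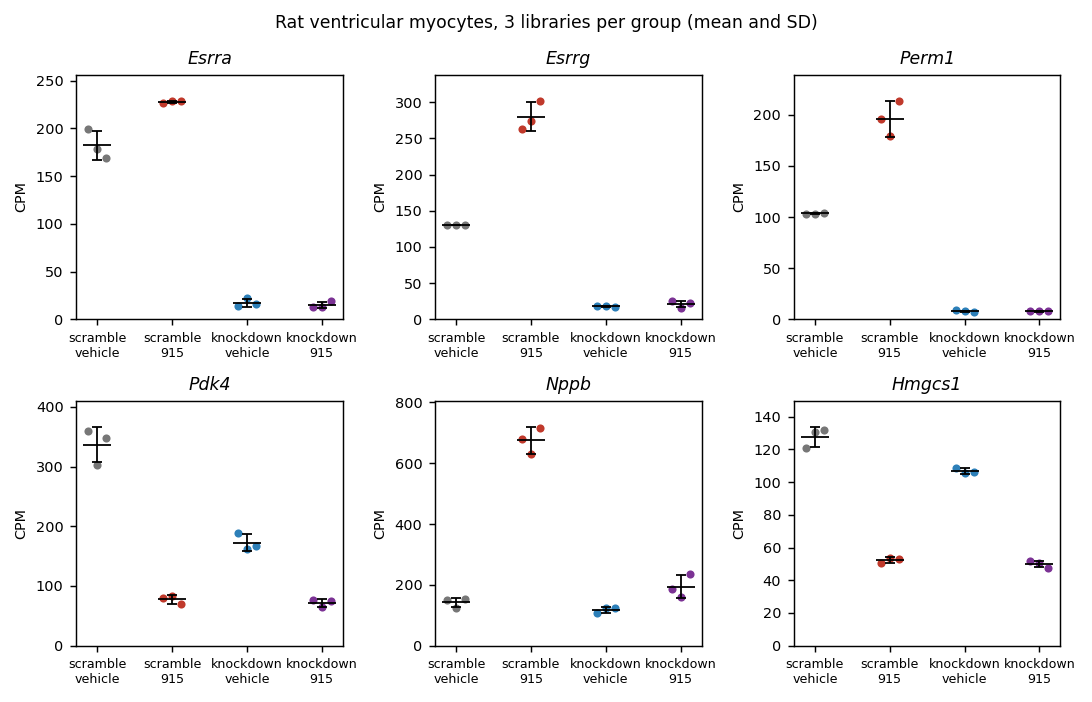
Expression in CPM of 6 genes in each rat library (points), with the group mean and SD of 3 libraries (bars). Esrra and Esrrg stayed at or below 25.1 CPM in all 6 knockdown libraries, Perm1 averaged 196 CPM with 915 and 104 CPM with vehicle in scramble cells, and Pdk4 and Hmgcs1 were lower with 915 in both backgrounds.

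The effect of 915 was then read in cells with intact receptors, which asks which genes the agonist moves. In scramble myocytes the metallothionein genes, whose proteins bind zinc and copper, rose most among the genes named by the rule: Mt2A went from 82.2 ± 5.10 to 641 ± 21.8 CPM (SD, n = 3; log2 2.96, SE 0.08). The annotation holds Mt1 under 2 identifiers with log2 changes of 3.32 (SE 0.19) and 3.26 (SE 0.11), and reads shared between them make the split uncertain. Nppb, the gene of the natriuretic peptide BNP, rose from 143 ± 15.5 to 675 ± 43.9 CPM (log2 2.24, SE 0.15), Trh by 2.53 (SE 0.23) and Fa2h by 2.23 (SE 0.25). The lowest fold changes among the genes named by the rule (mean of at least 5 CPM, CPM ranges that did not overlap) included those of Ucp3, a mitochondrial carrier induced by fatty acids, at −3.16 (SE 0.23), Cyp1a1, the classical target of the aryl hydrocarbon receptor, at −3.02 (SE 0.24), and Osr1, a transcription factor of mesenchymal cells, at −2.72 (SE 0.16). Smoc1 at −2.56 (SE 0.11), Samd9l at −2.49 (SE 0.23) and the interferon-induced Mx1 at −2.74 (SE 0.49) were also low, with Mx1 spread widely among vehicle libraries (199 ± 131 CPM).

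Within the ERR family and its coactivators 4 of 7 genes rose and none fell. Esrrg rose by 1.10 (SE 0.09), Perm1 by 0.92 (SE 0.06), Esrrb by 0.81 (SE 0.24) and Ppargc1b by 0.60 (SE 0.10). Esrra at 0.32 (SE 0.14, adjusted p = 0.0979; 5.87e-05 with only the groups compared) and Ppargc1a at 0.04 (SE 0.10, adjusted p = 0.771) did not pass. The list's adjusted p of 0.000841 became adjusted p = 0.0879 with an estimated correlation. Respiratory chain genes rose in 55 of 66 cases and none fell (59 rose when adjusted over the list alone), with Cox6a2 at 0.84 (SE 0.07) and Ndufs7 at 0.63 (SE 0.05). Their adjusted p of 1.51e-13 became adjusted p = 0.221 with an estimated correlation. Mitochondrially encoded genes rose in 11 of 13 cases, with Mt-nd5 at 0.61 (SE 0.10), and the mitochondrial share of counts was 7.65% ± 0.133 against 6.13% ± 0.539 in vehicle cells (adjusted p = 0.336 for the list with an estimated correlation). In the TCA cycle 11 of 19 genes rose and 1 fell (adjusted p = 0.365 with an estimated correlation), and 12 of 18 biogenesis, dynamics and antioxidant genes rose (adjusted p = 0.182 with an estimated correlation), among them Ppif at 0.92 (SE 0.08).

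Fatty acid oxidation genes moved the other way, with 20 of 29 lower and 1 higher (median −0.37). Pdk4, the kinase that shuts pyruvate dehydrogenase, fell from 337 ± 29.5 to 77.5 ± 6.91 CPM (log2 −2.12, SE 0.09). Decr1 changed by −1.47 (SE 0.07), Acaa2 by −0.84 (SE 0.05) and Cpt1a by −0.77 (SE 0.05), while Cpt1b was 0.15 (SE 0.07, adjusted p = 0.0928). The list's adjusted p of 1.04e-12 became adjusted p = 0.144 with an estimated correlation. Ketone and branched-chain amino acid oxidation had 13 of 18 genes higher and 1 lower. Oxct1, which lets heart cells burn ketone bodies, rose by 1.18 (SE 0.05; adjusted p = 0.152 for the list with an estimated correlation). Glycolysis had 12 of 22 genes higher and none lower, with Hk2 at 1.24 (SE 0.05) and Slc2a1 at 1.10 (SE 0.05), and adjusted p = 0.182 with an estimated correlation.

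Cardiac stress markers rose in 11 of 15 cases and fell in 3 (adjusted p = 0.0318 with an estimated correlation). Xirp2, an actin-binding protein, rose by 1.85 (SE 0.07), Gdf15 by 1.14 (SE 0.05) and Nppa by 0.68 (SE 0.12), while Actn1 changed by −1.04 (SE 0.06). Integrated stress response genes rose in 12 of 16 cases and fell in 1, with Ddit3 at 0.85 (SE 0.06) and Atf4 at 0.61 (SE 0.04; adjusted p = 0.165 for the list with an estimated correlation). Cholesterol synthesis genes fell in 13 of 15 cases and none rose (adjusted p = 0.000443 with an estimated correlation). Idi1, an isomerase of the pathway, changed by −1.75 (SE 0.11) and Hmgcs1, an early enzyme, by −1.28 (SE 0.06). Extracellular matrix genes fell in 18 of 24 cases and none rose, with tenascin (Tnc) at −1.67 (SE 0.08), Acta2 at −1.28 (SE 0.07) and fibronectin (Fn1) at −1.04 (SE 0.08), and adjusted p = 0.0652 with an estimated correlation. Of 8 smooth muscle and pericyte markers 7 fell and none rose (adjusted p = 0.0273 with an estimated correlation), such as Myh11 at −1.96 (SE 0.11) and Lmod1 at −1.83 (SE 0.08). Beside them the fibroblast markers had 7 of 12 lower and 1 higher (adjusted p = 0.0353, and adjusted p = 0.32 with an estimated correlation), while endothelial markers (2 lower and 1 higher of 9) and leukocyte markers (1 higher of 7) did not pass.

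Autophagy and lysosome genes rose in 12 of 29 cases and fell in 3, with the cargo receptor Sqstm1 at 0.98 (SE 0.05) and adjusted p = 0.144 for the list with an estimated correlation. Adult contraction genes split into 7 higher and 5 lower of 23 (adjusted p = 0.464), among them Actc1 at 0.77 (SE 0.07) and Kcnj2 at −1.13 (SE 0.12), and Myh6 at −0.30 (SE 0.12, adjusted p = 0.0709) and Myh7 at −0.05 (SE 0.13, adjusted p = 0.786) did not pass. Inflammatory genes (3 higher and 5 lower of 13), immediate early genes (5 higher and 2 lower of 13), clock genes (7 higher of 15) and the aryl hydrocarbon and oxidative stress list (5 higher and 4 lower of 12) did not pass as lists, nor did cell cycle genes (2 higher and 9 lower of 28). Among their members Lcn2 rose by 1.88 (SE 0.08), Hmox1 by 0.84 (SE 0.05) and Nr4a1 by 1.03 (SE 0.06), while Cyp1b1 changed by −2.05 (SE 0.09). In all, 6400 of 15181 genes passed the edgeR test, 3268 higher and 3132 lower, with 212 at least 2-fold higher and 682 at least 2-fold lower. Of 23 lists 15 passed and 3 still passed with an estimated correlation. The median, mean and test differed in sign for the aryl hydrocarbon, endothelial and leukocyte lists, none of which passed. In the authors' deposited comparison 5862 genes had an adjusted p below 0.05, 5695 of them called here too, with 0 of opposite sign.

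**Figure D2:**
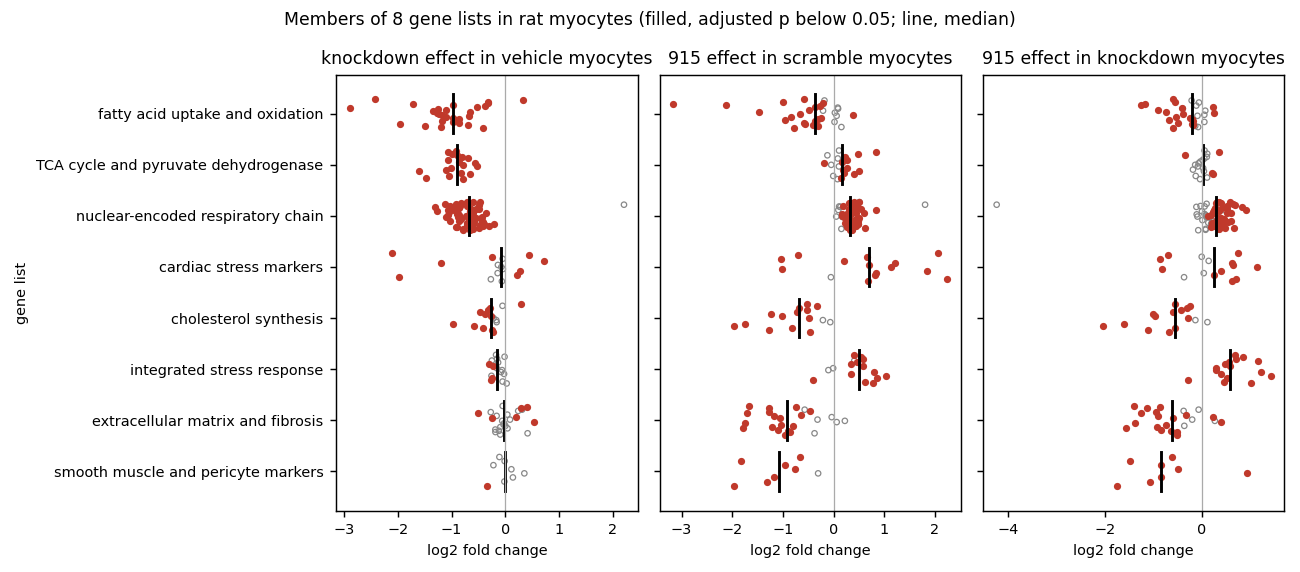
Log2 fold changes of the tested members of 8 gene lists in 3 rat comparisons, with filled points for an adjusted p below 0.05 and a line at the median. The fatty acid list had a median of −0.98 with the knockdown, −0.37 with 915 in scramble cells and −0.21 with 915 in knockdown cells, and the respiratory chain list −0.68, 0.33 and 0.31.

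Setting the agonist beside the knockdown asks whether 915 raised the genes that depend on the receptors. Both comparisons use the scramble vehicle libraries, and 1901 genes were called in both. Of these, 940 rose with 915 and fell with the knockdown, against 414 by independent lists of these sizes, and 422 fell with 915 and rose with the knockdown, against 242.6. Another 234 rose in both (253.2 by independent lists) and 305 fell in both (396.7). The first class held 55 of the 66 respiratory chain genes, 11 of 19 TCA cycle genes and 4 of the 7 ERR family genes, and the class that fell in both held 20 of the 29 fatty acid oxidation genes and 10 of the 15 cholesterol genes. Across genes the fold changes had a Pearson r of 0.0764 and a covariance of 0.0211. Simulated unchanged groups against the same vehicle libraries gave a mean r of 0.506 and a covariance of 0.048, so the observed covariance lay 0.0269 lower. The shared vehicle libraries push both comparisons to the same sign (33.1% of genes opposite in the simulation against 54% observed), and at most 1 gene was called in both there. They thus do not account for the genes of opposite sign. Genes are not independent replicates, and 3 vehicle libraries are too few to split.

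The 915 effect was also read in cells with ERR alpha and ERR gamma knocked down, which asks how much of it remains when the receptor transcripts are low. In knockdown myocytes the metallothionein genes rose again, with Mt2A at 2.60 (SE 0.08) and the 2 Mt1 entries at 3.12 (SE 0.19) and 3.02 (SE 0.11). Hamp, the gene of the iron hormone hepcidin, rose by 2.26 (SE 0.13), Lcn2, an iron carrier of innate immunity, by 2.11 (SE 0.07) and Trh by 2.03 (SE 0.21). Cyp1a1 changed by −3.40 (SE 0.26), Aqp7, a glycerol channel, by −2.34 (SE 0.17), Osr1 by −2.33 (SE 0.16) and Itga4 by −2.04 (SE 0.21), with n = 3 libraries per group. None of the 7 ERR family and coactivator genes passed by edgeR. Esrra was at −0.20 (SE 0.19, adjusted p = 0.483; 0.473 by DESeq2) and Esrrb at 0.71 (SE 0.29, adjusted p = 0.0579; 0.0823 by DESeq2), while Perm1 was 7.87 ± 0.219 CPM with 915 and 8.05 ± 0.606 CPM with vehicle. Esrrg at 0.22 (SE 0.12, adjusted p = 0.181) passed without the knockdown 915 library of replicate 2 (log2 0.39, adjusted p = 0.000629).

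Respiratory chain genes rose in 42 of 66 cases and none fell, with Cox6a2 at 0.92 (SE 0.07) and Ndufs7 at 0.66 (SE 0.05), and the list's adjusted p of 5.79e-12 became adjusted p = 0.353 with an estimated correlation. Mitochondrially encoded genes rose in 9 of 13 cases (adjusted p = 0.507 with an estimated correlation), and the mitochondrial share of counts was 6.39% ± 0.451 against 4.87% ± 0.398. Of the TCA cycle genes 3 rose and 1 fell out of 19, and that list did not pass (adjusted p = 0.816). Fatty acid oxidation genes fell in 17 of 29 cases and rose in 2, with Pdk4 at −1.26 (SE 0.09) and Acsl1 at −0.91 (SE 0.06), and adjusted p = 0.274 with an estimated correlation. Cholesterol synthesis genes fell in 13 of 15 cases (adjusted p = 0.00055 with an estimated correlation), with Hmgcs1 at −1.10 (SE 0.06). Integrated stress response genes rose in 15 of 16 cases and fell in 1, among them Chac1 at 1.24 (SE 0.10) and Atf3 at 1.02 (SE 0.08), and adjusted p = 0.0811 with an estimated correlation. Smooth muscle markers fell in 7 of 8 cases and rose in 1 (adjusted p = 0.0482 with an estimated correlation), and matrix genes fell in 16 of 24 and rose in 2, with Tnc at −1.40 (SE 0.08) and adjusted p = 0.102 with an estimated correlation.

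Immediate early genes rose in 8 of 13 cases and fell in 1, with Nr4a1 at 1.26 (SE 0.07). Clock genes rose in 8 of 15 cases, with Ciart at 1.01 (SE 0.11), and autophagy and lysosome genes rose in 14 of 29 and fell in 5, with Ctsd at 0.48 (SE 0.05). These 3 lists had adjusted p of 0.102, 0.102 and 0.117 with an estimated correlation. Cardiac stress markers rose in 8 of 15 cases and fell in 3, without passing as a list (adjusted p = 0.151), with Gdf15 at 1.13 (SE 0.05) and Nppb at 0.72 (SE 0.15). Myh6 changed by −1.01 (SE 0.12). Glycolysis (7 higher and 3 lower of 22), mitochondrial biogenesis (7 higher and 2 lower of 18), ketone and branched-chain amino acid oxidation (5 higher and 2 lower of 18), adult contraction (3 higher and 8 lower of 23) and cell cycle genes (5 lower of 28) did not pass, nor did the inflammatory (6 higher and 4 lower of 13), aryl hydrocarbon (5 and 5 of 12), fibroblast (2 and 3 of 12), endothelial (4 and 3 of 9) and leukocyte lists (2 higher of 7). The edgeR test called 5418 of 15181 genes, 2745 higher and 2673 lower, with 258 and 344 at least 2-fold. Of 23 lists 10 passed and 2 still passed with an estimated correlation. The median, mean and test differed in sign for the ERR family and fibroblast lists. The authors' deposited comparison had 4493 genes below 0.05, with 4407 in both and 0 of opposite sign.

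A direct test of the difference between the 2 agonist effects called 566 genes, 264 with a more positive and 302 with a more negative effect in knockdown cells. Several cardiac stress genes responded less in knockdown cells: Nppb differed by −1.53 (SE 0.20), Xirp2 by −1.44 (SE 0.09) and Spp1, the gene of osteopontin, by −1.43 (SE 0.16), and 7 of the 15 stress markers were called, all more negative (adjusted p = 0.0101 with an estimated correlation). Of the ERR family and coactivators 3 of 7 were called, all more negative (adjusted p = 0.0153 with an estimated correlation). Ucp3 differed by 1.99 (SE 0.32) and Mpeg1, a macrophage gene, by 1.49 (SE 0.27), both less lowered by 915 in the knockdown. Fatty acid oxidation genes differed upward in 8 of 29 cases and downward in 1 (adjusted p = 0.211 with an estimated correlation). Inflammatory genes had 3 of 13 more positive (adjusted p = 0.0153 with an estimated correlation). The TCA cycle had 3 of 19 more negative and the respiratory chain 4 of 66, with adjusted p of 0.173 and 0.62 with an estimated correlation. The cholesterol list differed in 1 of 15 genes (adjusted p = 0.0399, and adjusted p = 0.16 with an estimated correlation), and the integrated stress response in 1 more positive and 1 more negative of 16 (adjusted p = 0.314 with an estimated correlation). Of 23 lists 17 passed and these 3, the stress, ERR family and inflammatory lists, still passed with an estimated correlation. Among the others glycolysis had 6 of 22 genes more negative, ketone and branched-chain amino acid oxidation 2 of 18 with 1 more positive (10 more negative when adjusted over the list alone), matrix 3 of 24 more positive, fibroblast markers 2 of 12 more positive and smooth muscle markers 1 of 8 more positive. Their adjusted p were 0.168, 0.0741, 0.173, 0.132 and 0.173 with an estimated correlation.

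Of the genes called for 915 in scramble cells, 93.1% had the same sign in knockdown cells, and 4085 were called in both, 4047 with the same sign and 38 with opposite signs. Independent lists of these sizes would share 590.9 genes higher in both and 551.5 lower in both, against 2010 and 2037 observed. The slope of the knockdown on the scramble fold changes was 0.634. The count of 566 fell to 259 without the scramble 915 library of replicate 3, 305 without the knockdown vehicle library of replicate 1 and 359 without that of replicate 3, 321 without the scramble vehicle library of replicate 2 and 365 without the knockdown 915 library of replicate 2.

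**Figure D3:**
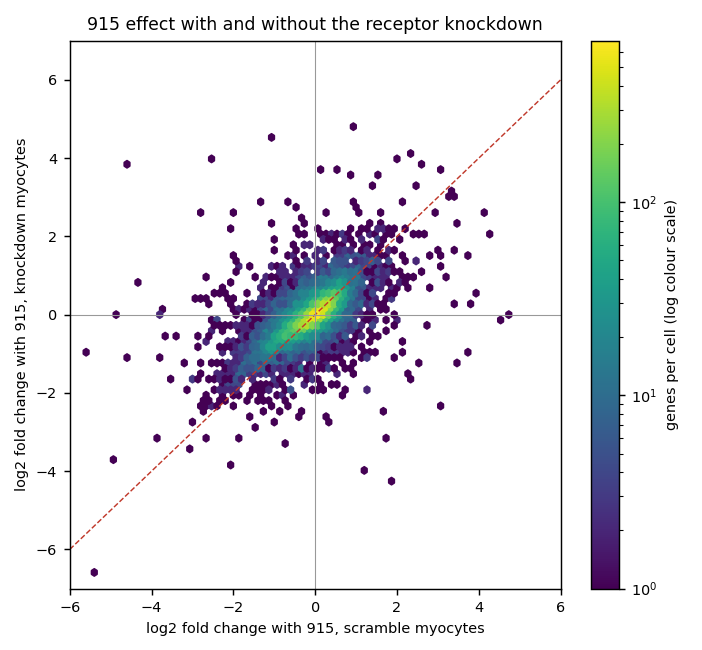
Log2 fold change with 915 in knockdown cells (vertical axis) against that in scramble cells (horizontal axis) for the 15181 genes tested, coloured by genes per cell on a log scale, with the dashed line of equal effects. Most genes lay along the diagonal at a slope below it (0.634 over the 6400 genes called in scramble cells).

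In mice, pressure overload was compared with sham surgery in vehicle-treated hearts. The natriuretic peptide genes rose, Nppa from 70.5 ± 41.7 CPM (SD, n = 3) to 1284 ± 648 CPM (n = 5) and Nppb from 50.2 ± 11.2 to 402 ± 111 CPM, with log2 changes of 3.96 (SE 0.78) and 3.13 (SE 0.31). Acta1, the skeletal actin re-expressed in overloaded hearts, rose by 4.55 (SE 0.51) and the slow myosin Myh7 by 3.11 (SE 0.61). Matrix genes rose strongly, with Cilp at 4.74 (SE 0.65), Ltbp2 at 4.74 (SE 0.99), Thbs4 at 4.22 (SE 0.89), Col8a1 at 2.88 (SE 0.45) and Col1a1 at 1.99 (SE 0.35). Dio2, which activates thyroid hormone, rose by 4.51 (SE 0.95). The lowest fold changes among the genes named by the rule were those of Cenpf at −2.95 (SE 0.34), Inmt at −2.73 (SE 0.55), the chloride channel Clcn1 at −2.64 (SE 0.43) and Lgals4 at −2.54 (SE 0.39). Hspa1a had a fold change of 4.79 (SE 1.58, adjusted p = 0.0396), shares reads with Hspa1b, and no longer passed without any 1 of the 3 sham vehicle libraries (adjusted p = 0.106, 0.11 and 0.116).

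As groups, 14 of 15 cardiac stress markers and 22 of 25 matrix genes rose and none fell, with adjusted p = 0.119 and 0.243 with an estimated correlation. Of the 31 fatty acid genes 21 fell and none rose (median −0.46), with Etfb at −0.82 (SE 0.11) and Decr1 at −0.68 (SE 0.11). Respiratory chain genes fell in 67 of 73 cases, TCA cycle genes in 15 of 20 and ketone and branched-chain amino acid genes in 15 of 18. These 4 lists had adjusted p of 0.353, 0.309, 0.353 and 0.353 with an estimated correlation. Among their members Ndufv1 changed by −0.48 (SE 0.07; −0.32 and adjusted p = 0.116 without the run term), Suclg1 by −0.50 (SE 0.09) and Bckdhb by −0.80 (SE 0.13), while Bdh1, a ketone body dehydrogenase, rose by 1.68 (SE 0.22). Of the 13 mitochondrially encoded genes 4 fell, and the mitochondrial share of counts in first-run hearts was 32.81%, 33.64% and 34.79% in TAC vehicle and 35.35%, 35.6% and 36.04% in sham vehicle, while the 2 second-run TAC vehicle hearts had 25.62% and 23.65%. Adult contraction genes fell in 11 of 26 cases and rose in 3, with the calcium store protein Casq2 at 0.54 (SE 0.09). The adjusted p of these 2 lists were 0.511 and 0.353 with an estimated correlation.

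The immediate early genes rose in 5 of 12 cases, with Myc at 1.51 (SE 0.31), and cell cycle genes rose in 8 of 25 and fell in 1, with Top2a at 1.64 (SE 0.32). Integrated stress response genes rose in 5 of 14 cases and fell in 1, with Mthfd2 at 1.89 (SE 0.33). Fibroblast markers rose in 7 of 12 cases and fell in 2, with Col15a1 at 1.59 (SE 0.22), and leukocyte markers rose in 3 of 13 (8 of 13 adjusted over the list alone). The adjusted p of these 5 lists were 0.353, 0.542, 0.119, 0.243 and 0.452 with an estimated correlation. Clock genes fell in 8 of 15 cases and rose in 4 (adjusted p = 0.353 with an estimated correlation), with Clock at 0.87 (SE 0.13), Hlf at −1.94 (SE 0.36) and Tef at −1.01 (SE 0.20). The ERR family did not pass, Esrra at −0.13 (SE 0.07, adjusted p = 0.158), Esrrg at 0.17 (SE 0.14, adjusted p = 0.395) and Ppargc1a at −0.04 (SE 0.23, adjusted p = 0.911). Lists for mitochondrial biogenesis (6 lower of 20), glycolysis (3 higher and 5 lower of 22), autophagy (8 higher and 3 lower of 29), inflammation (3 higher and 1 lower of 13), the aryl hydrocarbon response (4 and 4 of 12) and cholesterol synthesis (1 and 1 of 15) did not pass. The same held for endothelial (3 higher and 1 lower of 12), smooth muscle (1 lower of 8) and blood, adipocyte and nerve markers (2 lower of 10), and the sex-linked genes (1 lower of 4) were too few for a list test.

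The edgeR test called 3703 of 14047 genes, 1900 higher and 1803 lower, and 14 of 24 lists passed, none of them with an estimated correlation. The TAC vehicle hearts also differed in clock state: the clock score was 0.498 to 2.06 in these 5 hearts and −1.36 to −0.769 in the 3 sham vehicle hearts. With that score as a further term, chosen after seeing the data, 48 genes were called, among them Flnc at 0.88 and Nppb at 2.24. The clock list then took the opposite direction (adjusted p = 0.133 by camera), as did Socs3 at −0.00506 and Tef at 0.0144. The score is built from the clock genes, Tef among them, so what is left of the clock list and Tef under it is no separate test. It also did not overlap between TAC vehicle and sham vehicle hearts, so the term cannot be cleanly separated from TAC. The drop to 48 genes thus does not tell how many calls followed the clock. Without the sham vehicle library of replicate 3 the main count of 3703 became 2437.

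**Figure D4:**
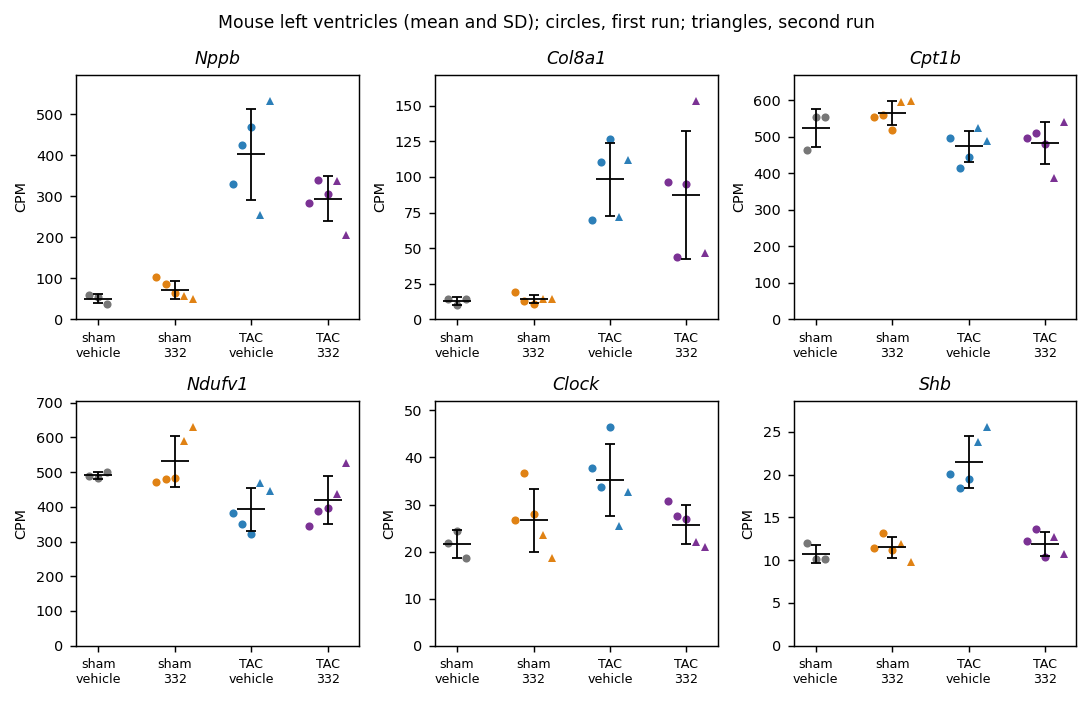
Expression in CPM of 6 genes in each mouse heart, with the group mean and SD (5 hearts per group, 3 for sham vehicle), circles for the first sequencing run and triangles for the second. Nppb averaged 402 CPM in TAC vehicle and 50.2 CPM in sham vehicle hearts, and Shb averaged 21.5 CPM in TAC vehicle and 11.9 CPM in TAC 332 hearts.

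The 332 agonist was tested in the overloaded hearts, which asks whether it moved genes away from their TAC level. Kcnh2, the hERG potassium channel, rose from 28.7 ± 4.397 to 45.1 ± 6.08 CPM (SD, n = 5; log2 0.65, SE 0.10), Tspan4 by 0.69 (SE 0.10), Smim5 by 0.79 (SE 0.12) and Arl4d by 0.75 (SE 0.12). Shb, a signalling adaptor, changed by −0.84 (SE 0.10), Ypel2 by −0.73 (SE 0.10), Pakap, an anchor of protein kinase A, by −0.72 (SE 0.12) and Chac1, an enzyme that degrades glutathione, by −1.74 (SE 0.26). The metalloprotease Adam19 at −1.26 (SE 0.22) and the collagen gene Col5a3 at −1.16 (SE 0.22) also passed, but adjusted p rose to 0.0749 and 0.0861 without the TAC 332 library of replicate 2. The receptor genes did not pass, nor did Pdk4 and Cpt1b: Esrra was at 0.11 (SE 0.06, adjusted p = 0.44), Esrrg at −0.12 (SE 0.12, adjusted p = 0.733), Pdk4 at −0.18 (SE 0.43, adjusted p = 0.913) and Cpt1b at 0.03 (SE 0.08, adjusted p = 0.92). Among the overload markers Nppb was at −0.46 (SE 0.22, adjusted p = 0.414), Myh7 at −0.50 (SE 0.44, adjusted p = 0.693) and Nppa at 0.13 (SE 0.54, adjusted p = 0.953).

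The edgeR test called 60 genes, 19 higher and 41 lower, against 10 genes in the first run alone and 3 in the second run alone, 13 without the run term and 183 by DESeq2. All 49 of the genes that were also called for TAC had the opposite sign there, 31 of them higher with TAC and lower with 332. Both comparisons use the TAC vehicle hearts, which pushes them apart: across genes r was −0.411 against −0.426 in the simulation, and the covariance −0.098 against −0.0542. With replicates 1, 2 and 4 of the vehicle hearts kept for the TAC comparison and 3 and 5 for 332, 205 genes were called for 332 and all 130 shared genes were opposite. The reverse division gave 11 genes for 332 and 8 shared, 7 of them opposite. Replicates 3 and 5 had the highest clock scores of the vehicle hearts, 2.06 and 2.04 against 0.498 to 0.863. They also had the highest means of the scaled cardiac stress markers, 1.13 and 1.47 against 0.404 to 0.845. The first division thus set both the clock state and these markers apart. The TAC vehicle hearts stood apart in clock state from the TAC 332 hearts, with scores of 0.498 to 2.06 against −0.608 to 0.183. With the clock score as a further term, chosen after seeing the data, edgeR called 0 genes (973 at unadjusted p under 0.05, and 183 by DESeq2 without that term). All 60 genes kept their sign under it, with a median absolute fold change of 0.439 against 0.603, while the median SE over all genes went from 0.112 to 0.162.

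Of the fixed lists 7 passed and none passed with an estimated correlation. Respiratory chain genes were higher by a median of 0.11 with 0 of 73 called, leukocyte markers had a median of −0.37 with 0 of 13 called (7 lower when adjusted over the list alone), and matrix genes a median of −0.26 with 0 of 25 called. Their adjusted p were 0.839, 0.23 and 0.839 with an estimated correlation. Clock genes had a median of 0.45 with 0 of 15 called (9 higher and 4 lower when adjusted over the list alone), blood, adipocyte and nerve markers 0.65 with 0 of 10 called, cell cycle genes −0.06 with 0 of 25, and the integrated stress response −0.18 with 1 of 14 called, Chac1. These 4 had adjusted p of 0.565, 0.565, 0.839 and 0.23 with an estimated correlation. Hemoglobin and Alas2 transcripts, which come from blood and share reads among near-identical genes, were highest in the TAC 332 heart of replicate 2, with Hbb-bs at 749 CPM against 249 to 447 CPM in the other 4. Every TAC 332 heart lay above every TAC vehicle heart, where Hbb-bs was at 140.5 to 218.9 CPM. Hba-a1 (447.4 to 1107 against 228.1 to 358.9 CPM) and Alas2 (14.07 to 40.56 against 8.159 to 13.34 CPM) were likewise apart. These genes lie outside the naming rule and were chosen after their values were seen. They describe a separation in these hearts and do not test a difference in blood transcripts between the groups. With the clock score term, chosen after seeing the data, the respiratory chain, matrix, cell cycle and clock lists took the opposite direction (adjusted p = 0.391, 0.00225, 0.543 and 0.0263 by camera), and 10 lists passed. The score is built from the clock genes, so it gives no separate test of the clock list. It also did not overlap between TAC vehicle and TAC 332 hearts, so the term cannot be cleanly separated from the treatment, and these reversals decide nothing about the lists. The 17 other lists tested, the fatty acid, TCA cycle, ERR family and cardiac stress lists included, did not pass.

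Without any 1 of several hearts the count of 60 moved by more than 1.5 times, to 22 without the TAC vehicle heart of replicate 1 or of replicate 5, 31 without that of replicate 3, and 39, 94 and 25 without the TAC 332 hearts of replicates 3, 4 and 5.

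**Figure D5:**
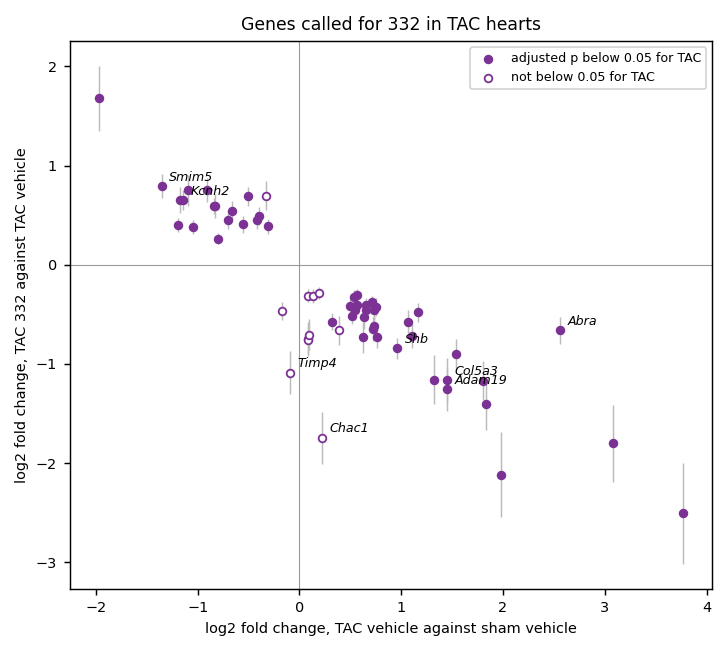
Log2 fold change of the 60 genes called for 332 in TAC hearts (vertical axis, bars give the SE) against their fold change for TAC (horizontal axis), filled where the TAC change had an adjusted p below 0.05. All 49 filled genes lay in the 2 quadrants of opposite sign, and both axes share the TAC vehicle hearts.

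In sham hearts 332 changed 1 gene by edgeR and 5 by DESeq2. By edgeR 685 of 14047 genes had an unadjusted p under 0.05, no more than the share of 0.05 that chance alone would give. Myh3, the embryonic skeletal myosin, had a log2 change of 4.86 (SE 0.60, adjusted p = 0.000693), a gene outside the naming rule chosen after its values were seen. It stood at 6.54, 7.15 and 6.27 CPM in the 3 sham 332 hearts sequenced on 1 lane and at 0 and 0.145 CPM in the other 2, with 0.0740 to 0.313 CPM in sham vehicle hearts. These 3 hearts, replicates 1 to 3, were alone on that lane, the sham vehicle hearts were on another, and the other 2 sham 332 hearts were in a run without sham vehicle hearts. The 332 effect in sham hearts was thus confounded with the lane. Myh3 no longer passed without any 1 of replicates 1 to 3: no gene passed without the first or the second, and 1 other gene without the third. Without the sham vehicle heart of replicate 1, 2 genes passed. The ERR family list had a median of 0.24 with 0 of 7 called, with Esrra at 86.6 ± 3.95 CPM (n = 5) against 73.4 ± 2.60 CPM (n = 3; log2 0.18, SE 0.07, adjusted p = 0.914), and cholesterol synthesis a median of 0.15 with 0 of 15 called. Both lists passed at the preset correlation (adjusted p = 0.000839 and 0.011) but had adjusted p of 0.253 and 0.0871 with an estimated correlation. The other 22 lists tested did not pass.

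The difference between the 332 effects in TAC and sham hearts was called for 9 genes, 3 more positive and 6 more negative with TAC (87 by DESeq2). This contrast takes in the 332 effect in sham hearts, so its genes and lists share that effect's confounding with the lane. Slc46a3, a lysosomal transporter, differed by 1.36 (SE 0.23), Tspan4 by 0.94 (SE 0.15) and Gramd1b, a sterol carrier, by 0.64 (SE 0.12), whereas Clock differed by −0.92 (SE 0.17), Shb by −0.91 (SE 0.17), the chaperone Hyou1 by −0.68 (SE 0.12) and Stk24 by −0.65 (SE 0.12). The respiratory chain, matrix, clock and leukocyte lists passed with medians of 0.13, −0.33, 0.75 and −0.36, and had adjusted p of 0.709, 0.709, 0.481 and 0.421 with an estimated correlation. The first 3 took the opposite direction with the clock score term (adjusted p = 0.0877, 0.000455 and 0.00268 by camera). That score is built from the clock genes, so the last value is no separate test of the clock list. These 9 calls rested on single hearts. None of the 9 remained without any 1 of 9 hearts (sham 332 replicates 2 and 4, sham vehicle 1, 2 and 3, TAC 332 3 and 5, TAC vehicle 1 and 3), and 1 remained without sham 332 replicate 1. Without TAC vehicle replicate 5, TAC 332 replicate 2 or TAC 332 replicate 4, 2, 3 and 4 of the 9 remained. Without sham 332 replicate 3 or TAC vehicle replicate 2, 25 and 20 genes were called, 9 and 8 of them among the 9. The first run alone gave 5 genes by edgeR, none of them among the 9, and the clock score term, chosen after seeing the data, 0 (768 of 14047 at unadjusted p under 0.05, close to the share that chance alone would give).

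The 2 agonists were given to different species, preparations and times, so their effects stand side by side and no difference between the compounds was tested. Of 10731 symbols tested in both, 30 were called for 915 in scramble myocytes and for 332 in TAC hearts, 13 with the same and 17 with the opposite sign (odds ratio 1.6, p = 0.119, two-sided Fisher's exact test across genes). Of the 50 genes called for 332 that had a rat counterpart, 25 had the same sign with 915. Nppb, which is not among these 50, rose by 2.24 (SE 0.15) with 915 in myocytes and was at −0.46 (SE 0.22) with 332 in TAC hearts, where it did not pass. With 915 and TAC 1659 symbols were shared, 679 with the same and 980 with the opposite sign. Of these, 395 rose in both (417.9 by independent lists of these sizes) and 284 fell in both (315.3). Another 431 rose with 915 and fell with TAC (349.8), and 549 fell with 915 and rose with TAC (376.7). Across genes the Pearson r was −0.0869.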

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

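Of the tests in this part, those of residual receptors and of the lower matrix and smooth muscle genes were chosen only after the result was seen, and the test of uneven remodelling was added after a high split count was seen.

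The genes called for 332 in TAC hearts moved away from the TAC vehicle hearts, whose clock scores were the highest of the 4 groups, so a difference in collection time or clock state could have produced them. Among the other 13 hearts 73.3% of the 60 genes had the slope on the clock score needed for this, against a median of 55% and a 95th percentile of 65% in random gene sets, but the slope gave a median of 22.6% of the fold change, and the question stays open. Uneven remodelling among the TAC hearts may have played a part, yet 60% of the genes had the slope needed, within the range of random sets, with 1.61% of the fold change given, which leaves it open. A difference between the runs likely plays little part: of 341 genes with p below 0.01 by edgeR in the first run, 85.6% had the same sign in the second. Chance could not be excluded, because 5 of 100 label splits called as many genes as the real 60, with a highest other count of 899 for a split that put TAC 332 replicates 3 and 4 with TAC vehicle replicates 2, 3 and 5, which points to a structure of the samples. These 5 hearts had the highest means of the scaled cardiac stress markers, 0.828 to 1.47 against 0.264 to 0.638 in the other 5 TAC hearts, so that split followed these markers.

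Most 915 effects persisted in knockdown cells, and receptor left after the knockdown might explain them if effects scaled with its transcripts. The slope of knockdown on scramble fold changes was 0.634 (0.608 to 0.662 over resampled genes), against 18.1 ± 0.599 CPM of Esrrg left from 131 CPM. For the cholesterol list the slope was 0.903 (0.784 to 0.977), and for the integrated stress response 1.23 (0.983 to 1.46), lists picked after their effects were seen to persist. Other lists shrank: the median of the cardiac stress markers went from 0.704 in scramble to 0.263 in knockdown cells, of the TCA cycle from 0.166 to 0.0305, of fatty acid oxidation from −0.366 to −0.207 and of the matrix from −0.929 to −0.622, while the respiratory chain went from 0.33 to 0.305. An effect in proportion to the transcripts was taken to allow at most 0.5, and all 3 slopes lay above that. Only the last lay above 0.8 by more than its spread, the limit first set against this explanation. These spreads resample genes of the same libraries and do not measure the spread over libraries. With lists picked for persisting, the slopes do not decide whether it was the whole cause. A part in the effects that shrank stays open, as does receptor protein left in the cells, since transcripts do not measure it. Targets other than ERR alpha and gamma could account for such genes, and no library here tests that.

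The lower matrix and smooth muscle genes with 915 could reflect fewer cells other than myocytes. Endothelial markers had a median of 0.262 while smooth muscle markers had −1.07, fibroblast markers −0.398 and leukocyte markers −0.0991, but the endothelial mean was 0.00584, with 2 members lower and 1 higher, so a loss of other cells stays open. The scaling of the libraries was not tested: RLE size factors moved the median gene by 0.0086 log2, but they rest on the same assumption as TMM. Lower transcription within cells may also play a part.

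For the 3 two-group rat comparisons the 10 splits of 3 against 3 were too few to exclude chance: 1 of 10 splits called as many genes as the real 6400 for 915 in scramble cells (highest other 0), 1 of 10 as many as 5418 for 915 in knockdown cells (highest other 0) and 1 of 10 as many as 3099 for the knockdown (highest other 1). For the difference of the 915 effects 4 of 100 splits called as many as 566, with a highest other of 2195. Such splits mix the treatments and so hold their effects, and they are no test of chance, which stays open. For TAC 1 of 56 splits, the real one, reached 3703 (highest other 1426), which argues against chance. Such splits cannot tell TAC from the clock state, which also differed between these hearts. For 332 in sham hearts 5 of 56 splits reached 1 gene, with a highest other of 9 for the split that set sham 332 replicates 4 and 5 with the sham vehicle hearts. Chance could not be excluded there, and that split separates the 3 sham 332 hearts of 1 lane of the first run, with 12 genes called within the first run. For the difference of the 332 effects 2 of 100 splits reached 9, with a highest other of 39, and these splits also mix the treatments and leave chance open.

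The difference of the 915 effects was called for 566 genes, with values of 1.988 for Ucp3, 1.488 for Fam181b, 1.487 for Mpeg1, −1.641 for Gnb3, −1.528 for Nppb, −1.44 for Xirp2 and −1.429 for Spp1. The difference of the 332 effects was called for 9 genes, with 1.361 for Slc46a3, 0.9358 for Tspan4, 0.6408 for Gramd1b, −0.9216 for Clock, −0.9106 for Shb, −0.6841 for Hyou1 and −0.6461 for Stk24.

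Single libraries stood apart for 18 of 351 group values, where about 1 in 20 would do so by chance. TAC 332 replicate 4 had Myh7 at 5306 CPM (others 927.1 to 1461), Ltbp2 at 135.5 (13.57 to 45.6), Meox1 at 42.38 (14.07 to 22.07), Dio2 at 27.19 (4.48 to 8.024) and Pdk4 at 164.4 (343.2 to 414.4). TAC 332 replicate 3 had Cldn5 at 13.12 CPM (8.065 to 8.829), Cd14 at 2.778 (2.317 to 2.438) and Bub1 at 0.7715 (0.1224 to 0.2825). Sham 332 replicate 3 had Col15a1 at 43.6 CPM (61.02 to 62.12), Col1a1 at 25.86 (40.89 to 41.95) and Vcam1 at 20.92 (12.67 to 15.06), and sham 332 replicate 5 had Esrrg at 31.11 CPM (40.07 to 42.75). Hspa1a, which shares reads with Hspa1b, stood at 119.2 CPM in TAC 332 replicate 2 (1.716 to 5.65) and at 62.21 CPM in TAC vehicle replicate 3 (7.88 to 21.75). TAC vehicle replicate 5 had Myc at 6.12 CPM (4.617 to 4.779) and Pakap at 73.31 (42.1 to 48.83), TAC vehicle replicate 1 had Ppargc1a at 150 CPM (62.52 to 79.12), and TAC 332 replicate 5 had Myl2 at 8126 CPM (5406 to 5990).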

How the results depend on the processing

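The clock score term and the removal of mitochondrially encoded genes were chosen only after the result was seen, and the other alternatives before the data were examined. Called named genes kept their direction in every setting except the clock score term, where the TAC fold changes of Socs3 and Tef became −0.00506 and 0.0144. For 332 in TAC hearts 60 genes were called, against 671 without the low-count filter, 183 by the Wald test of DESeq2, 30 with only the groups compared, 13 without the run term, 10 in the first run, 3 in the second run and 0 with the clock score term. Of the 671, 34 genes were not tested in the filtered fit, and the prior degrees of freedom went from 8.91 to infinity. For 332 in sham hearts 1 gene was called, against 191 without the filter, 5 by DESeq2, 28 with only the groups compared, 0 without the run term and 12 in the first run. For the difference of the 332 effects 9 genes were called, against 521 without the filter, 87 by DESeq2, 0 without the run term, 5 in the first run and 0 with the clock score term. The TAC count of 3703 became 48 with the clock score term, and 3527 genes kept their sign. The median standard error went from 0.136 to 0.23 there, and the median absolute fold change of the called genes from 0.517 to 0.309. That score did not overlap between TAC vehicle and sham vehicle hearts, nor between TAC vehicle and TAC 332 hearts. Its term can thus not be cleanly separated from TAC or from 332 in TAC hearts. The second run held no sham vehicle heart and gave no value for TAC, 332 in sham or the difference, and only the groups compared gave none for the 2 differences of effects, which need all 4 groups. The cause of the other changes in count was not tested.

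With 1 library left out, counts ran from 5536 to 5896 for 915 in scramble cells, 4627 to 5056 for 915 in knockdown cells, 2338 to 2765 for the knockdown and 259 (without scramble 915 replicate 3) to 677 (without knockdown 915 replicate 3) for the difference of the 915 effects, with 305, 321, 359 and 365 in between without knockdown vehicle replicate 1, scramble vehicle replicate 2, knockdown vehicle replicate 3 and knockdown 915 replicate 2. They ran from 2437 to 3747 for TAC, 22 to 94 for 332 in TAC, 0 to 2 for 332 in sham and 0 to 25 for the difference of the 332 effects.

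Of the lists that passed, an estimated correlation left 3 of 15 for 915 in scramble cells, 2 of 10 for 915 in knockdown cells, 10 of 13 for the knockdown, 3 of 17 for the difference of the 915 effects, and 0 for TAC, 0 for 332 in TAC, 0 for 332 in sham and 0 for the difference of the 332 effects. With the clock score term 6 lists passed for TAC, 10 for 332 in TAC (7 without it, 6 of the 10 not passing before), 13 for 332 in sham and 10 for the difference. Under it 8 list results that had passed without the term changed direction, and lists that had not passed were left out of this count. The clock list then had an adjusted p by camera of limma of 0.133 for TAC, 0.0263 for 332 in TAC and 0.00268 for the difference. Because the score is built from the clock genes, these clock list values are no separate test of that list. For 332 in TAC the respiratory chain then had 0.391, the matrix 0.00225 and the cell cycle 0.543, and for the difference the respiratory chain 0.0877 and the matrix 0.000455. At an adjusted p below 0.01 the overlaps were 1151 genes for 915 and the knockdown, 13 for TAC and 332, 7 for 915 and 332 and 814 for 915 and TAC.

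With the replicate number as a block, 6276, 5292, 2941 and 542 genes were called for the 4 rat comparisons in the order above, 3356 for TAC, 40 for 332 in TAC, 1 for 332 in sham and 6 for the difference of the 332 effects, and the list calls changed only for that difference, with 1 lost and 1 gained. The numbers share no pairing: 1 of 18 rat pairs correlated above 0.1 (−0.147 to 0.145), 2 of 12 rat libraries correlated best with their own number, and in mouse 1 of 24 pairs did so once the run was removed (−0.518 to 0.136).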

Other observations

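The gene lists of this part, interferon-stimulated genes, the metal response, chaperones of the endoplasmic reticulum, skeletal muscle genes and PPAR targets, were chosen only after the result was seen. The first 4 were drawn up around genes already seen to change, so only counts and medians are given for them. Interferon-stimulated genes, part of the antiviral defence, fell with 915 in scramble myocytes in 28 of 31 cases (median −1.45), such as Oas2 at −2.08, Bst2 at −2.06, Irf7 at −1.51 and Isg15 at −1.35. In knockdown myocytes 22 of 31 fell (median −0.745). Metal response genes, the metallothioneins, zinc exporters and their regulator Mtf1, rose in 4 of 6 cases in scramble cells (median 1.61) and in 2 of 6 in knockdown cells (median 0.867). The list takes 1 of the 2 entries of Mt1.

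In the mouse hearts chaperones of the endoplasmic reticulum rose with TAC in 10 of 22 cases and fell in 1 (median 0.245). With 332 in TAC hearts 4 of 22 fell, Hspa5 at −0.31, Hyou1 at −0.41, Manf at −0.51 and Creld2 at −0.61 (median −0.218). The list was written after these 4 were seen and holds them, and both comparisons use the TAC vehicle hearts. In sham hearts 0 of 22 were called with 332 (median 0.0262). Skeletal muscle genes were higher in sham 332 hearts by a median of 2.03 with 1 of 11 called, and that gene, Myh3, was high only in the 3 sham 332 hearts of 1 lane (6.27 to 7.15 CPM) and at 0 and 0.145 CPM in the 2 sham 332 hearts of the second run, so within the treatment it followed the lane or run.

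Lower fatty acid oxidation genes with 915 could reflect lower transcription of PPAR targets at large. Of 14 PPAR targets outside the fatty acid list 6 fell (42.9%) and 2 rose, with a median of −0.157. Tested as a list by camera in scramble cells, they had p = 0.00042, and p = 0.0188 with an estimated correlation. In knockdown cells 5 fell and 2 rose, with a median of −0.0245. The limits set beforehand, 60% lower and a median of −0.3 or less in both kinds of cells, were not met, nor were those for excluding it, so the question stays open. Angptl4 changed by −1.54 in scramble and −0.515 in knockdown cells and Aqp7 was called lower too, whereas Plin4 at 0.17 and Cyp4b1 at 0.63 rose. A receptor binding assay for 915 across nuclear receptors would separate these.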
